A study of Mus musculus with 12 samples.

How the data were processed

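Total RNA of M2-10B4 cells was poly(A)-selected and made into strand-specific libraries (KAPA, Roche) that were sequenced on an Illumina HiSeq instrument in paired-end runs of 150 cycles, per the labels' protocols. The 12 samples form 4 groups of 3 biological replicates, taken from the sample titles and treatment labels: control, DHT, ADM and ADM+DHT, each on day 9, with medium and DHT replaced at regular intervals. The composition of the regular medium is not stated. The title of 1 ADM+DHT sample is spelled differently from its fellows and was read as ADM+DHT replicate 2. The submitters' processing notes name FastQC, cutadapt, HISAT2 and StringTie, with no versions, and the mouse genome build GRCm38.

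The authors deposited 4 tables, each for a pair of groups. Per the file headers they hold FPKM for each library, made by the authors, and all genes in them are protein-coding. In each table every gene has a mean of at least 0.5 FPKM in a group, as checked on the values. The group columns in the deposited tables were found to equal the mean over the 3 libraries of log2(FPKM + 1), and the authors' log2 fold change to equal their difference. The authors' fold change is the ratio 2 to the power of that difference. The authors' p-value and q-value come from a test that no header or label names, so they are quoted only as counts. The values of a library were the same in every table (largest difference 0), so the tables were joined by gene identifier: 12028 genes occur in any table and 11582 have values in all 12 libraries. A single line of each table (1 per table) was emptied before it was received for this work. A symbol shared by several identifiers occurs 11 times and such genes were kept apart by identifier, and the identifier listed as Nrg4 in 1 of the 4 tables and as Nrg2 in the other 3 was called Nrg2. Coordinates are those of the deposited tables in GRCm38. Of the 12028 identifiers, 12010 are in GENCODE release M21 and 11026 have the same start and end there.

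No counts are in the tables and the depth of each library is unknown. A search for FPKM values that are whole multiples of a smallest value found at most 24.0% of 150 low genes per library within a tolerance of 0.05, too few to recover counts, so no counting intervals are given. Precision rests on the 3 replicates of each group. Genes outside the deposited tables were not analysed here.

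From the FPKM values, log2(FPKM + 1) was computed and tested with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), with moderated variances that follow an intensity trend. A gene was tested where its mean was at least 1 FPKM in a compared group. Each of the 4 pairs was fitted on its 6 libraries (4 residual degrees of freedom). The interaction of DHT and medium, (ADM+DHT minus ADM) minus (DHT minus control), was fitted on all 12 (8 residual degrees of freedom). Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes tested in a comparison, and "changed", "rose" and "fell" mean an adjusted p below 0.05. Counts at 1.5-fold or more are given beside them. Errors of group means are SD and errors of log2 differences are SE from limma. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

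Gene lists, 25 in number, were fixed before the data were examined, as were the comparisons, tests, filters, the rule for named genes and the alternatives, except where said otherwise. They cover adipocyte identity, fatty acid and triglyceride synthesis, lipid droplet and lipolysis, brown and beige fat, fatty acid oxidation, cholesterol synthesis and uptake, osteoblast, chondrocyte, bone marrow stromal and niche, preadipocyte and adipogenesis inhibitors, androgen response, glucocorticoid response, and steroid receptors and steroid metabolism. The others are the Wnt pathway, the TGF-beta and BMP pathway, extracellular matrix, myofibroblast and smooth muscle, cell cycle, interferon response, inflammatory cytokines and proteases, hypoxia and glycolysis, the unfolded protein and oxidative stress response, and markers of skeletal muscle, macrophage and haematopoietic, and endothelial cells. A gene may be on several lists. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated per list, which with 6 libraries is a noisy estimate. Members are also counted after adjustment over the list alone.

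Genes were named by rule. For each pair these were the 8 largest rises and 8 largest falls (5 and 5 for the interaction) among changed genes with no overlap between the compared groups' libraries, at least 5 FPKM in the higher group, and a symbol that is more than a clone or identifier. The rule adds the up to 4 members of each list with the smallest adjusted p, and 10 genes always, among them Fkbp5, Pparg, Cebpa, Fabp4, Adipoq, Lpl, Runx2, Alpl and Cxcl12. Some genes that the rule names are not reported here. Genes with near-identical copies, such as the Orm, Akr1c, Klk1b, Ces1 and Hist1h2a families, are less certain, since the sources do not say how reads shared between copies were assigned.

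The overlap of changed genes between comparisons was set against the product of the marginal counts, with Fisher's exact test only where the comparisons share no library. Where they share libraries, 20 simulations of replicate noise with no effect gave the correlation and covariance that sharing alone produces.

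The fits were tested on simulated data with 200 changed genes planted in the real genes' means and variances. For ADM+DHT against ADM (10823 genes), 68.7% of genes planted at 1.5-fold, 94% at 2-fold and 98.5% at 4-fold were recovered, and 7.4% of calls were false. For ADM against control (11074 genes) the shares were 85.1%, 94% and 97%, with 6.6% false. For DHT against control (10820 genes) they were 71.6%, 91% and 100%, with 6.9% false, and for ADM+DHT against DHT (10942 genes) 67.2%, 91% and 100%, with 5% false. For the interaction (11152 genes) they were 46.3%, 85.1% and 95.5%, with 2.6% false.

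The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, replicate number as a block, no intensity trend, rescaling of each library to a median log2 ratio of 0, quantile normalization, all 12 samples in 1 fit, a fold of at least 1.5 for the overlaps, an estimated correlation for the lists, and leaving out each library in turn. Leaving out the 13 mitochondrially encoded genes with rescaling, the correlation estimated in the fit of all 12 samples, the interaction on genes of at least 1 or 5 FPKM in a group of each medium, and the division of shared libraries between comparisons, were added after the data were examined.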

Results

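RNA sequencing measured messenger RNA in M2-10B4 cells, an established mouse stromal cell line from bone marrow (C57BL/6J X C3H/HeJ). The cells were cultured for 9 days in 4 conditions, with 3 biological replicates each and 12 libraries in all. Control cells were kept in regular medium. DHT cells received 10 nM dihydrotestosterone, a potent androgen, in the same medium. ADM cells were kept in adipogenic medium with 2 µg/mL insulin, 1 µM dexamethasone, 2 µM rosiglitazone and 10% charcoal-stripped serum, and ADM+DHT cells received the androgen in that medium. Dexamethasone is a synthetic glucocorticoid, and rosiglitazone activates the fat cell transcription factor encoded by Pparg. The series title places the work in androgen action during the passage of stromal cells to adipocytes.

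The tables give FPKM of protein-coding genes and no read counts, so the depth of each library is unknown. FPKM summed to between 240651 and 262947 per library, and 10502 to 10633 genes lay above 1 FPKM. Transcripts of the 13 mitochondrially encoded genes made up 9.57% ± 0.34 of all FPKM in control, 10.1% ± 0.45 in DHT, 16.8% ± 0.42 in ADM and 13.6% ± 0.31 in ADM+DHT (mean ± SD, n = 3 each). Across 11338 genes, which are not independent replicates, Pearson's r of log2 values was 0.989 to 0.991 between libraries of a group and 0.877 to 0.972 between libraries of different groups. Group means correlated with r = 0.978 for control and DHT, 0.973 for ADM and ADM+DHT, 0.884 for control and ADM, 0.899 for control and ADM+DHT, 0.911 for DHT and ADM, and 0.943 for DHT and ADM+DHT. Differences between groups are log2 differences of FPKM with 1 added, given ± SE, so they understate the fold of genes near 0.

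The comparison of ADM with control asks what adipogenic medium changed in these cells. The composition of the regular medium is not stated, so the comparison covers every difference between the media. Fat cell genes were far higher in ADM. Adipoq (ENSMUSG00000022878.5, chromosome 16, 23146536 to 23158028 in GRCm38), which encodes the hormone adiponectin, stood at 0.914 ± 0.161 FPKM in control and 549.9 ± 21.8 in ADM (mean ± SD, n = 3 each), a log2 difference of 8.17 ± 0.069. Fabp4 (ENSMUSG00000062515.3, chromosome 3, 10204088 to 10208576), a fatty acid carrier, went from 2.94 ± 0.144 to 624 ± 4.11 FPKM, a difference of 7.31 ± 0.041. The lipid droplet proteins Cidec and Plin1 rose by 8.07 ± 0.055 and 6.403 ± 0.057, and the fatty acid transporter Cd36 by 6.81 ± 0.065. Other large rises were those of the oxidase gene Cyp2e1 at 7.23 ± 0.104, of Gpd1 (ENSMUSG00000023019.12, chromosome 15, 99717515 to 99725005), whose enzyme makes glycerol phosphate for triglycerides, at 6.82 ± 0.097, and of the sulfotransferase gene Sult1a1 at 6.53 ± 0.055. The transcription factors of fat cell formation rose less, Pparg (ENSMUSG00000000440.12, chromosome 6, 115360951 to 115490399) from 8.28 ± 0.72 to 28.1 ± 1.53 FPKM and Cebpa (ENSMUSG00000034957.10, chromosome 7, 35119293 to 35121928) from 18.1 ± 8.22 to 72.8 ± 12.1. The control libraries of Cebpa were spread, at 8.62, 22.7 and 23 FPKM.

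Several genes of connective tissue and signalling fell in ADM. Dio2 (ENSMUSG00000007682.6, chromosome 12, 90724552 to 90738438), whose deiodinase activates thyroid hormone, dropped from 76.3 ± 2.5 to 0.878 ± 0.088 FPKM, a log2 difference of -5.36 ± 0.058. Tnmd, the tendon protein tenomodulin, had a difference of -4.30 ± 0.061, the microfibril gene Mfap4 of -4.26 ± 0.198, the membrane protein gene Emp1 (ENSMUSG00000030208.15, chromosome 6, 135362545 to 135383173) of -4.10 ± 0.1, and the retinoic acid carrier gene Crabp2 of -4.04 ± 0.099. Cdsn, Fndc1 and the growth factor gene Bmp4 were also among the largest falls, at -3.75, -3.30 and -3.19. The Bmp4 level in ADM differed between libraries, at 2.22, 5.86 and 2.41 FPKM. The niche chemokine gene Cxcl12 rose by 0.94 ± 0.054, and the osteoblast transcription factor gene Runx2 had a difference of -0.22 ± 0.08 (adjusted p = 0.0452), a call that ended under 4 other settings and without control replicate 3 or any 1 of the ADM replicates (adjusted p 0.0526 to 0.121).

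By list, the markers of adipocyte identity rose together: 29 of 30 tested members rose, 0 fell and 1 did not pass (29 and 0 adjusted over the list alone). They had a median log2 of 2.74 (adjusted p = 1.81e-17, and adjusted p = 0.041 with an estimated correlation). For the lipid droplet and lipolysis genes, 15 of 18 tested members rose, 1 fell and 2 did not pass (16 and 1 adjusted over the list alone), among them the triglyceride lipase gene Pnpla2 at 4.74 (median log2 2.24, adjusted p = 1.56e-09, and adjusted p = 0.041 with an estimated correlation). Fatty acid oxidation, the breakdown of fat in mitochondria, had a like pattern: 23 of 24 tested members rose, 1 fell and 0 did not pass (23 and 1 adjusted over the list alone). The list had a median log2 of 1.53 (adjusted p = 1.74e-11, and adjusted p = 0.16 with an estimated correlation). Examples are Acadm at 3.09 and Pdk4 at 3.30, and these rises went with the higher share of mitochondrially encoded transcripts in ADM. In fatty acid and triglyceride synthesis 16 of 24 tested members rose, 5 fell and 3 did not pass (16 and 6 adjusted over the list alone), including Thrsp at 4.75, Gpat3 at 2.53 and Dgat1 at 2.06 (median log2 0.98, adjusted p = 0.00159, and adjusted p = 0.18 with an estimated correlation). In the glucocorticoid response list, 27 of 29 tested members rose, 2 fell and 0 did not pass (27 and 2 adjusted over the list alone). Its members had a median log2 of 1.89 (adjusted p = 6.7e-14, and adjusted p = 0.055 with an estimated correlation). Its members Fkbp5 (ENSMUSG00000024222.16, chromosome 17, 28399095 to 28517524), a co-chaperone of steroid receptors, Glul and Tsc22d3 rose by 4.47, 4.998 and 3.71, in a medium that holds dexamethasone.

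The androgen response list, tested here without DHT, had a smaller shift: 33 of 69 tested members rose, 23 fell and 13 did not pass (34 and 24 adjusted over the list alone). They had a median log2 of 0.15 (adjusted p = 0.045, and adjusted p = 0.17 with an estimated correlation). That call also ended under 4 other settings (adjusted p 0.0513 to 0.0543) and without control replicate 2 or ADM replicate 2 (0.0669 and 0.0601). Steroid receptor and steroid metabolism genes gave a similar result: 10 of 21 tested members rose, 4 fell and 7 did not pass (10 and 4 adjusted over the list alone), with a median log2 of 0.15 (adjusted p = 0.045, and adjusted p = 0.17 with an estimated correlation), and other settings or a missing ADM replicate 1 or 2 moved it to between 0.0535 and 0.0989. Akr1c18, a progesterone-inactivating reductase with near-identical family members, rose by 4.17, and Hsd17b4 by 1.15. In the brown and beige fat list 4 of 6 tested members rose, 1 fell and 1 did not pass (4 and 1 adjusted over the list alone), and the list was not past the threshold (adjusted p = 0.221).

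Cell cycle genes were lower throughout. In ADM 0 of 39 tested members rose, 39 fell and 0 did not pass (0 and 39 adjusted over the list alone). The list had a median log2 of -1.99 (adjusted p = 1.26e-16, and adjusted p = 0.082 with an estimated correlation). The mitosis genes Cdc20, Birc5, Tpx2 and Kif20a had differences of -2.63, -2.55, -2.50 and -2.49. Interferon response genes, which are part of antiviral defence, were mostly lower: 2 of 30 tested members rose, 23 fell and 5 did not pass (2 and 24 adjusted over the list alone), with a median log2 of -0.88 (adjusted p = 1.25e-05, and adjusted p = 0.19 with an estimated correlation), as for Ifit3 at -2.61 and Bst2 at -2.20. Hypoxia and glycolysis genes were also mostly lower: 5 of 29 tested members rose, 21 fell and 3 did not pass (5 and 21 adjusted over the list alone). Its members had a median log2 of -0.99 (adjusted p = 0.000575, and adjusted p = 0.2 with an estimated correlation). Ldha and Pgk1, enzymes of glycolysis, differed by -1.53 and -1.38, while Egln3 rose by 1.94.

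Connective tissue genes mostly fell. Of the extracellular matrix genes, 10 of 42 tested members rose, 29 fell and 3 did not pass (10 and 29 adjusted over the list alone). They had a median log2 of -0.79 (adjusted p = 0.00114, and adjusted p = 0.17 with an estimated correlation). Fn1, which encodes fibronectin, and Timp3, an inhibitor of metalloproteases, differed by -2.73 and -2.55, while the basement membrane collagen gene Col4a1 rose by 1.91. Among osteoblast genes, 3 of 20 tested members rose, 15 fell and 2 did not pass (4 and 15 adjusted over the list alone). The list had a median log2 of -0.65 (adjusted p = 0.00972, and adjusted p = 0.16 with an estimated correlation). Col1a1 and Spp1, which encode bone matrix proteins, differed by -0.97 and -1.11, and Postn (ENSMUSG00000027750.16, chromosome 3, 54361109 to 54391037), the matrix protein periostin, rose by 1.58. In the TGF-beta and BMP pathway 5 of 30 tested members rose, 17 fell and 8 did not pass (5 and 17 adjusted over the list alone), with a median log2 of -0.36 (adjusted p = 0.0348, and adjusted p = 0.17 with an estimated correlation), and the call ended when only genes of at least 5 FPKM were tested (adjusted p = 0.0513).

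The other lists tested were not past the threshold in ADM. Cholesterol synthesis and uptake had 8 risen and 10 fallen of 24 tested (8 and 10 adjusted over the list alone), chondrocyte genes 2 risen and 4 fallen of 9 tested (2 and 4 adjusted over the list alone), niche genes 9 risen and 10 fallen of 19 tested (9 and 10 adjusted over the list alone), preadipocyte genes and adipogenesis inhibitors 9 risen and 10 fallen of 23 tested (9 and 10 adjusted over the list alone), Wnt pathway genes 11 risen and 10 fallen of 27 tested (11 and 10 adjusted over the list alone), and myofibroblast genes 6 risen and 10 fallen of 17 tested (6 and 10 adjusted over the list alone). Skeletal muscle genes had 1 risen and 4 fallen of 5 tested (1 and 4 adjusted over the list alone), inflammatory cytokines and proteases 5 risen and 11 fallen of 18 tested (5 and 11 adjusted over the list alone), and the unfolded protein and oxidative stress response 10 risen and 14 fallen of 31 tested (10 and 15 adjusted over the list alone). The niche and Wnt lists had negative medians and means but a test that pointed up. The preadipocyte list had a median of 0, a negative mean and a test that pointed down. Of other cell types, 4 macrophage and haematopoietic genes (0 rose, 2 fell) and 3 endothelial genes (1 rose, 2 fell) had enough signal to be tested, too few for a list test. In all, 6825 of 11074 genes tested changed, 3136 higher and 3689 lower, of which 1520 and 1590 changed at least 1.5-fold. The authors' deposited table for this pair has 2914 genes higher and 3435 lower at its own q below 0.05.

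Comparing ADM+DHT with ADM asks what the androgen did while the cells were in adipogenic medium. Fat cell genes were lower with DHT. Adipoq stood at 178 ± 11.5 FPKM in ADM+DHT against 549.9 ± 21.8 in ADM, a log2 difference of -1.63 ± 0.053, and Fabp4 at 255 ± 5.22 against 624 ± 4.11, a difference of -1.29 ± 0.027. Lpl (ENSMUSG00000015568.16, chromosome 8, 68880491 to 68907448), the lipoprotein lipase, had 32.6 ± 0.834 FPKM against 144 ± 3.93, and Gpd1 14.8 ± 1.17 against 161 ± 17.5, differences of -2.11 ± 0.037 and -3.36 ± 0.086. Pparg went from 28.1 ± 1.53 to 17.3 ± 0.879 FPKM, a difference of -0.67 ± 0.058. Cebpa differed by -2.31 ± 0.509 (adjusted p = 0.0121), with ADM+DHT libraries at 8.39, 35.9 and 8.31 FPKM.

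**Figure D1:**
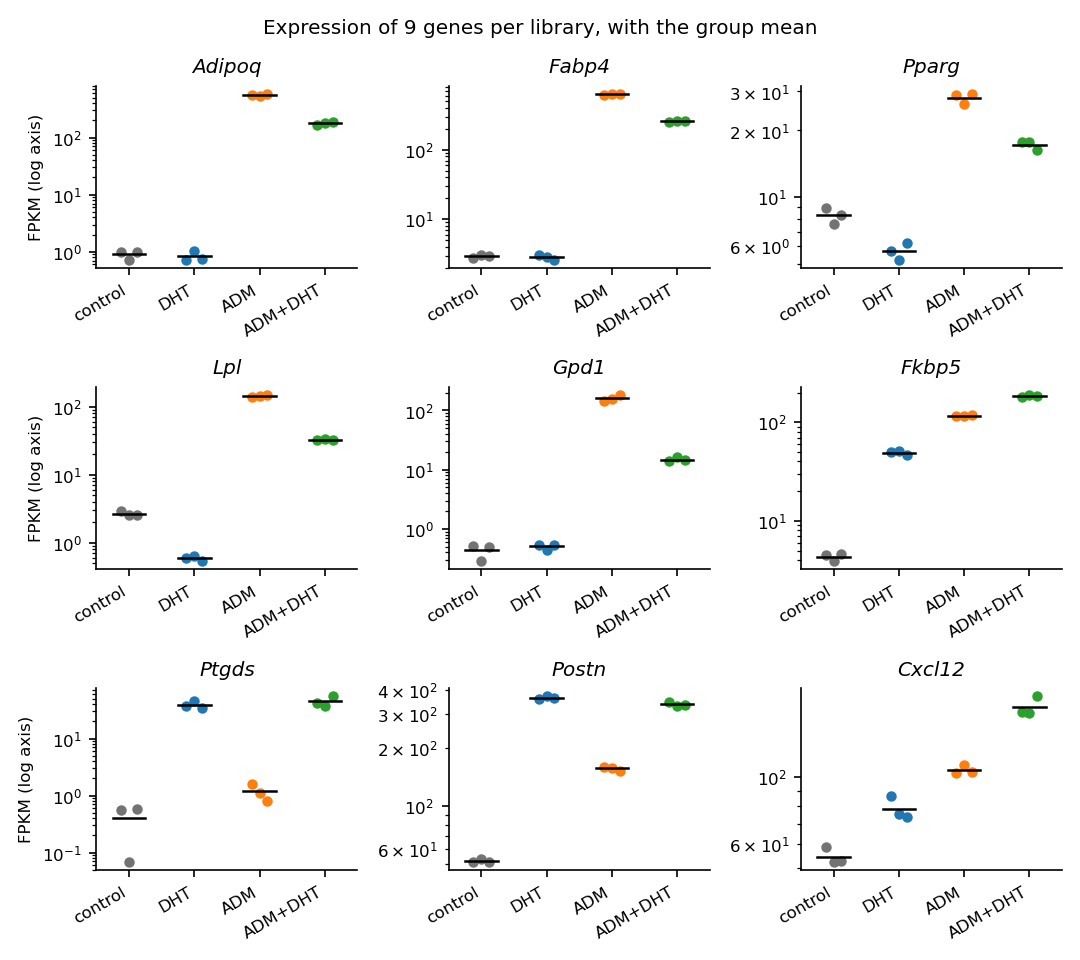
FPKM of 9 genes (log axis) in the 4 conditions, with a dot for each of the 3 libraries and a black bar for the group mean. Adipoq, Fabp4, Lpl and Gpd1 are highest in ADM and lower in ADM+DHT, where Adipoq averages 178 FPKM against 549.9, while Ptgds rises with DHT in both media.

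The largest fall was in Ephx2 (ENSMUSG00000022040.8, chromosome 14, 66084374 to 66124500), which encodes soluble epoxide hydrolase, from 42.0 ± 0.967 to 1.83 ± 0.355 FPKM (-3.93 ± 0.094). Retn, the adipocyte hormone resistin, the respiratory chain gene Cox8b, the lipase gene Ces1d and the carbonic anhydrase gene Car3 differed by -3.35 ± 0.07, -3.21 ± 0.235, -3.13 ± 0.131 and -2.73 ± 0.052. The amino acid transporter gene Slc36a2 and the phosphatase inhibitor gene Ppp1r1a completed the largest falls, at -2.81 and -2.78. Ces1d belongs to a family of similar genes that short reads can confuse. The largest rise was in Ptgds (ENSMUSG00000015090.13, chromosome 2, 25466709 to 25470046), a prostaglandin synthase, from 1.18 ± 0.404 to 45.1 ± 9.02 FPKM (4.40 ± 0.172), followed by Lypd8 (ENSMUSG00000013643.13, chromosome 11, 58379043 to 58390728) at 3.76 ± 0.129. The signalling regulator gene Ppp1r1b, the matrix gene Sparcl1 and the anion transporter gene Slc26a7 rose by 2.81 ± 0.087, 2.54 ± 0.062 and 2.30 ± 0.095. Orm3, an acute-phase protein gene, and the kallikrein gene Klk1b21, both with near-identical copies, rose by 2.93 and 2.77. Fkbp5 rose by 0.65 ± 0.031 from its level in ADM. Cxcl12 and Runx2 rose by 0.69 ± 0.055 and 0.26 ± 0.057.

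In the lists of fat metabolism most members fell with DHT. Of the adipocyte identity genes, 0 of 30 tested members rose, 27 fell and 3 did not pass (0 and 27 adjusted over the list alone). Its members had a median log2 of -1.30 (adjusted p = 8.05e-19, and adjusted p = 0.13 with an estimated correlation). The lipid droplet and lipolysis list counted as follows: 2 of 18 tested members rose, 14 fell and 2 did not pass (2 and 14 adjusted over the list alone), including the hormone-sensitive lipase gene Lipe at -1.73, Fitm2 at -1.39 and Cidec at -1.31 (median log2 -1.19, adjusted p = 8.72e-09, and adjusted p = 0.13 with an estimated correlation). For fatty acid and triglyceride synthesis, 2 of 24 tested members rose, 15 fell and 7 did not pass (4 and 16 adjusted over the list alone), such as Gpat3 at -1.74, Thrsp at -1.22 and Me1 at -0.96 (median log2 -0.51, adjusted p = 1.03e-05, and adjusted p = 0.13 with an estimated correlation). Among fatty acid oxidation genes, 2 of 24 tested members rose, 19 fell and 3 did not pass (2 and 20 adjusted over the list alone), with Acadl at -1.34, Etfdh at -1.13 and Acadm at -0.82 (median log2 -0.74, adjusted p = 1.87e-09, and adjusted p = 0.13 with an estimated correlation). These falls went with the lower share of mitochondrially encoded transcripts, 13.6% in ADM+DHT against 16.8% in ADM. Cholesterol synthesis and uptake genes were lower as well: 1 of 24 tested members rose, 17 fell and 6 did not pass (2 and 17 adjusted over the list alone), with a median log2 of -0.44 (adjusted p = 1.03e-05, and adjusted p = 0.13 with an estimated correlation), and Cyp51 and Nsdhl, enzymes of sterol synthesis, differed by -1.38 and -0.99. In the steroid receptor and steroid metabolism list, 3 of 20 tested members rose, 11 fell and 6 did not pass (3 and 12 adjusted over the list alone). They had a median log2 of -0.26 (adjusted p = 0.00734, and adjusted p = 0.14 with an estimated correlation). There the dehydrogenase genes Hsd17b10 and Hsd17b4 differed by -0.76 and -0.64, while Akr1c18 rose by 1.63.

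For the cell cycle genes, already low in ADM, 1 of 33 tested members rose, 15 fell and 17 did not pass (1 and 18 adjusted over the list alone). The list had a median log2 of -0.31 (adjusted p = 0.000642, and adjusted p = 0.33 with an estimated correlation). The proliferation marker gene Mki67 (-0.75) and the cyclin gene Ccne1 (-0.78) fell, and Rrm1 rose by 0.64. Among genes of at least 5 FPKM in a group the list was not past the threshold (adjusted p = 0.964). For hypoxia and glycolysis, 7 of 27 tested members rose, 13 fell and 7 did not pass (7 and 14 adjusted over the list alone). Its members had a median log2 of -0.20 (adjusted p = 0.0389, and adjusted p = 0.36 with an estimated correlation). Pfkfb3 and Hk2, regulators of glycolysis, differed by -1.62 and -1.09, and Ndrg1 by 1.32. This list was not past the threshold without ADM replicate 3 (adjusted p = 0.0811) or ADM+DHT replicate 3 (0.0604).

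More matrix and stromal genes rose than fell with DHT. Among extracellular matrix genes, 24 of 40 tested members rose, 6 fell and 10 did not pass (25 and 6 adjusted over the list alone). They had a median log2 of 0.35 (adjusted p = 5.41e-06, and adjusted p = 0.14 with an estimated correlation). Timp3, Fn1 and the collagen cross-linking gene Lox rose by 2.17, 1.12 and 0.79. The TGF-beta and BMP pathway gave the same direction: 14 of 27 tested members rose, 2 fell and 11 did not pass (17 and 2 adjusted over the list alone). The list had a median log2 of 0.37 (adjusted p = 2.53e-05, and adjusted p = 0.13 with an estimated correlation). Ctgf, a long-known TGF-beta target, rose by 2.07, and the ligand genes Inhba and Tgfb3 by 0.96 and 0.83. For osteoblast genes, 12 of 18 tested members rose, 3 fell and 3 did not pass (12 and 3 adjusted over the list alone), with a median log2 of 0.29 (adjusted p = 0.000688, and adjusted p = 0.13 with an estimated correlation): Postn rose by 1.10 and Omd by 0.98, and Enpp1 fell (-0.86). In the bone marrow stromal and niche list 8 of 18 tested members rose, 4 fell and 6 did not pass (8 and 4 adjusted over the list alone). Its members had a median log2 of 0.29 (adjusted p = 0.016, and adjusted p = 0.14 with an estimated correlation). Vcam1, an adhesion molecule for blood cells, Igfbp5 and Cdh11 rose by 1.19, 0.96 and 0.82.

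**Figure D2:**
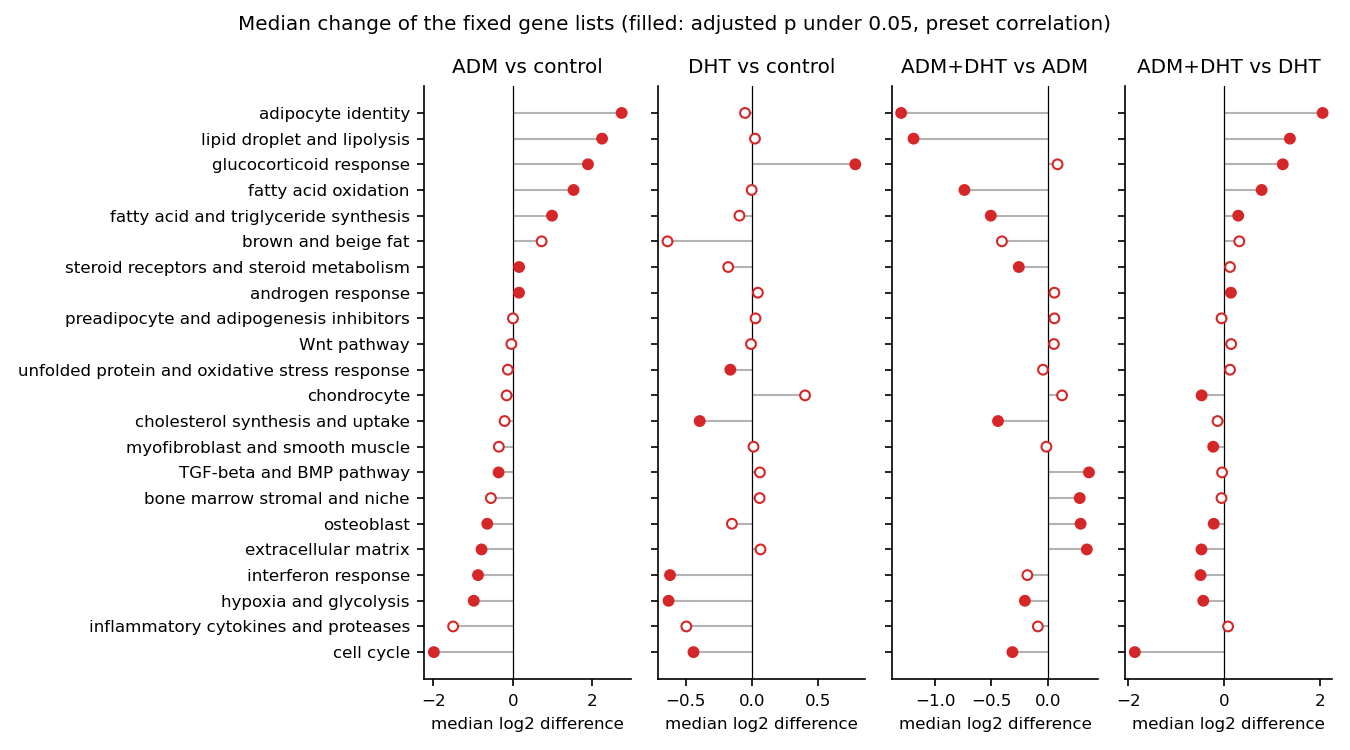
Median log2 difference (x axis, range set per panel) of the tested members of 22 gene lists in 4 comparisons, filled where the list test with preset correlation gave an adjusted p below 0.05 and open elsewhere. The adipocyte list has a median of 2.74 in ADM against control and -1.30 in ADM+DHT against ADM.

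The list fixed for androgen response did not move one way in ADM: 27 of 70 tested members rose, 16 fell and 27 did not pass (28 and 17 adjusted over the list alone). They had a median log2 of 0.06 (adjusted p = 0.219). The glucocorticoid response list had 13 risen and 9 fallen of 30 tested (15 and 9 adjusted over the list alone) and an adjusted p of 0.478, with the rising Rgs2 (1.01) and Crispld2 (0.90) beside the falling Sult1a1 (-0.94). Also not past the threshold were preadipocyte genes and adipogenesis inhibitors, with 9 risen and 3 fallen of 22 tested (9 and 4 adjusted over the list alone), Wnt pathway genes, with 9 risen and 5 fallen of 25 tested (11 and 5 adjusted over the list alone), chondrocyte genes, with 4 risen and 1 fallen of 8 tested (4 and 1 adjusted over the list alone), and brown and beige fat genes, with 1 risen and 3 fallen of 5 tested (1 and 3 adjusted over the list alone). Interferon response genes had 3 risen and 6 fallen of 27 tested (3 and 6 adjusted over the list alone), inflammatory cytokines and proteases 2 risen and 5 fallen of 14 tested (3 and 6 adjusted over the list alone), and the unfolded protein and oxidative stress response 8 risen and 10 fallen of 31 tested (9 and 11 adjusted over the list alone). Myofibroblast and smooth muscle genes had 4 risen and 2 fallen of 17 tested (4 and 2 adjusted over the list alone), with a negative median, a positive mean and a test that pointed up.

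In all, 3628 of 10823 genes tested changed between ADM+DHT and ADM, 1860 higher and 1768 lower, and 412 and 595 of these by at least 1.5-fold. The authors' deposited table has 1444 genes higher and 1387 lower at its q below 0.05. By camera with a correlation of 0.01 between genes, 12 of 22 lists passed, 4 up and 8 down. With the correlation estimated from these 6 libraries 0 passed after adjustment and 7 had an unadjusted p below 0.05. With it estimated from all 12 libraries 6 passed.

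The comparison of DHT with control shows the androgen's effect without adipogenic medium. The largest rises were in Lypd8, from 0.0817 ± 0.0833 to 38.5 ± 3.39 FPKM (5.19 ± 0.089), and Ptgds, from 0.398 ± 0.286 to 38.9 ± 5.45 (4.85 ± 0.168). Fkbp5 rose from 4.33 ± 0.365 to 49.2 ± 1.99 FPKM (3.24 ± 0.065). Postn rose from 52.0 ± 0.963 to 366 ± 5.87 FPKM (2.79 ± 0.032), and the calcium release gene Trdn, the secreted protein gene Crispld2, Ctla2a and the dipeptidase gene Dpep1 rose by 3.47 ± 0.107, 3.13 ± 0.166, 3.10 ± 0.116 and 3.02 ± 0.074. Dio2 fell from 76.3 ± 2.5 to 2.36 ± 0.218 FPKM (-4.53 ± 0.061), and Mmp13, a collagenase gene, from 122 ± 8.93 to 8.42 ± 1.11 (-3.71 ± 0.095).

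Other large falls were those of Emp1 at -3.13 ± 0.071, of the matrix genes Dpt and Mfap4 at -2.85 ± 0.069 and -2.76 ± 0.192, of the receptor gene Gfra1 at -1.88 ± 0.077, and of Chodl and Crabp2 at -1.90 and -1.76. Fat cell genes were low in both groups. Lpl fell from 2.66 ± 0.193 to 0.588 ± 0.0497 FPKM (-1.20 ± 0.076) and Pparg from 8.28 ± 0.72 to 5.72 ± 0.506 (-0.47 ± 0.085, adjusted p = 0.00671). Fabp4 differed by -0.04 (adjusted p = 0.764) and Adipoq was below 1 FPKM in both groups and was not tested. Cebpa differed by -0.21 (adjusted p = 0.686), which became -0.65 (0.000778) without control replicate 1. Cxcl12 and the alkaline phosphatase gene Alpl rose by 0.52 ± 0.072 and 0.88 ± 0.095. Runx2 differed by -0.14 (adjusted p = 0.27).

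The glucocorticoid response list rose with DHT in regular medium: 25 of 28 tested members rose, 3 fell and 0 did not pass (25 and 3 adjusted over the list alone). The list had a median log2 of 0.78 (adjusted p = 2.34e-15, and adjusted p = 0.027 with an estimated correlation). Besides Fkbp5 and Crispld2, Sult1a1 rose by 2.59, the glutamine synthetase gene Glul by 1.64 and the metallothionein gene Mt2 by 1.34. It was the only one of the 22 lists tested to pass upward. In the androgen response list, 20 of 67 tested members rose, 17 fell and 30 did not pass (22 and 17 adjusted over the list alone). Its members had a median log2 of 0.05 (adjusted p = 0.22). Selenop of the androgen response list rose by 1.06, and Fst, which is also on the TGF-beta list, by 2.25. Examples from other lists that rose were Omd at 1.45 and Ctgf of the TGF-beta list at 1.09.

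The lists that passed downward hold genes of cell division, glycolysis, interferon, sterol synthesis and protein stress. For the cell cycle, 0 of 39 tested members rose, 34 fell and 5 did not pass (0 and 37 adjusted over the list alone), with a median log2 of -0.44 (adjusted p = 4.21e-16, and adjusted p = 0.027 with an estimated correlation), among them Ccnb2 at -0.71, Top2a at -0.55 and Tpx2 at -0.52. Hypoxia and glycolysis genes followed: 1 of 29 tested members rose, 22 fell and 6 did not pass (1 and 23 adjusted over the list alone), with a median log2 of -0.63 (adjusted p = 3.86e-12, and adjusted p = 0.027 with an estimated correlation), such as Ldha at -0.90, Pgk1 at -0.83 and Bnip3 at -0.73. In the interferon response, 0 of 30 tested members rose, 25 fell and 5 did not pass (0 and 26 adjusted over the list alone). Interferon response genes had a median log2 of -0.62 (adjusted p = 1.16e-13, and adjusted p = 0.061 with an estimated correlation). Gbp3, Ifit1 and Bst2 differed by -1.61, -1.58 and -1.34. Of cholesterol synthesis and uptake genes, 1 of 24 tested members rose, 15 fell and 8 did not pass (1 and 18 adjusted over the list alone), with a median log2 of -0.39 (adjusted p = 4.55e-07, and adjusted p = 0.15 with an estimated correlation), and the pathway enzymes Cyp51, Idi1 and Sqle differed by -0.65, -0.59 and -0.59. For the unfolded protein and oxidative stress response, 3 of 31 tested members rose, 12 fell and 16 did not pass (3 and 14 adjusted over the list alone), with a median log2 of -0.16 (adjusted p = 0.00436, and adjusted p = 0.41 with an estimated correlation), with Trib3 at -0.76 and Atf5 at -0.40, while the peroxidase gene Prdx6 rose by 0.43.

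The remaining lists were not past the threshold in DHT against control. Among these, adipocyte identity genes had 3 risen and 5 fallen of 18 tested (3 and 6 adjusted over the list alone), lipid droplet and lipolysis genes 0 risen and 2 fallen of 13 tested (0 and 2 adjusted over the list alone), fatty acid oxidation genes 5 risen and 3 fallen of 23 tested (5 and 3 adjusted over the list alone), osteoblast genes 7 risen and 8 fallen of 22 tested (8 and 10 adjusted over the list alone), niche genes 9 risen and 6 fallen of 19 tested (9 and 6 adjusted over the list alone), and extracellular matrix genes 15 risen and 14 fallen of 42 tested (18 and 17 adjusted over the list alone). In the lipid droplet, fatty acid oxidation, osteoblast and niche lists the median and the mean had opposite signs. In all, 2907 of 10820 genes tested changed, 1376 higher and 1531 lower, with 358 and 323 at 1.5-fold or more. The authors' deposited table has 992 genes higher and 1096 lower at its q below 0.05.

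ADM+DHT against DHT shows what adipogenic medium did when the androgen was present throughout. Fat cell genes rose here too. Adipoq went from 0.841 ± 0.182 to 178 ± 11.5 FPKM (6.60 ± 0.082), Fabp4 from 2.84 ± 0.239 to 255 ± 5.22 (6.06 ± 0.053), and Lpl from 0.588 ± 0.0497 to 32.6 ± 0.834 (4.41 ± 0.056). Cidec, Cyp2e1, Akr1c18, Cd36 and Plin1 rose by 6.50 ± 0.073, 5.98 ± 0.077, 5.42 ± 0.075, 4.87 ± 0.08 and 4.64 ± 0.129. Mki67 had the largest fall, from 41.7 ± 0.489 to 3.89 ± 0.771 FPKM (-3.14 ± 0.104), followed by the cartilage gene Ucma at -3.03 ± 0.083, the gelatinase gene Mmp9 at -2.95 ± 0.08 and Fndc1 at -2.83 ± 0.06. The other largest falls were of near-identical histone genes that poly(A) libraries capture poorly, Hist1h2ap, Hist1h2ao, Hist1h2ag and Hist1h2ah, at -2.97, -2.86, -2.79 and -2.76.

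Fkbp5, Pparg and Cxcl12 rose by 1.88 ± 0.038, 1.44 ± 0.072 and 1.12 ± 0.074, and Alpl fell (-0.84 ± 0.144). Cebpa differed by -0.05 ± 0.5 (adjusted p = 0.948), and without ADM+DHT replicate 2 by -0.71 (0.000217). Runx2 differed by 0.18 (adjusted p = 0.0539), with adjusted p of 0.0314 to 0.0499 under 5 other settings and 0.0364 without DHT replicate 2.

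Fat and glucocorticoid lists passed upward again. For adipocyte identity, 24 of 27 tested members rose, 0 fell and 3 did not pass (24 and 0 adjusted over the list alone), with a median log2 of 2.05 (adjusted p = 7.65e-16, and adjusted p = 0.045 with an estimated correlation). For lipid droplets and lipolysis, 15 of 17 tested members rose, 0 fell and 2 did not pass (15 and 0 adjusted over the list alone), with a median log2 of 1.37 (adjusted p = 4.99e-10, and adjusted p = 0.03 with an estimated correlation), as for Pnpla2 at 3.13. In fatty acid oxidation, 20 of 23 tested members rose, 0 fell and 3 did not pass (20 and 1 adjusted over the list alone), with a median log2 of 0.78 (adjusted p = 2.11e-10, and adjusted p = 0.03 with an estimated correlation), as for Acadm at 2.02 and Pdk4 at 2.10, next to a mitochondrially encoded share of 13.6% against 10.1%. Fatty acid and triglyceride synthesis had 13 risen and 5 fallen of 22 tested (14 and 5 adjusted over the list alone), with a median log2 of 0.29 (adjusted p = 0.0113, and adjusted p = 0.13 with an estimated correlation). For the glucocorticoid response, 28 of 30 tested members rose, 2 fell and 0 did not pass (28 and 2 adjusted over the list alone), with a median log2 of 1.22 (adjusted p = 1.92e-15, and adjusted p = 0.03 with an estimated correlation), as for Glul at 2.96 and Ddit4 at 2.12. The androgen response list had 32 risen and 17 fallen of 70 tested (34 and 18 adjusted over the list alone), with a median log2 of 0.14 (adjusted p = 0.01, and adjusted p = 0.066 with an estimated correlation), and its members Zbtb16 and Selenop rose by 3.17 and 1.63.

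The lists that passed downward were those of cell division, interferon, glycolysis and connective tissue. For the cell cycle, 0 of 39 tested members rose, 38 fell and 1 did not pass (0 and 38 adjusted over the list alone), with a median log2 of -1.87 (adjusted p = 2.93e-19, and adjusted p = 0.066 with an estimated correlation), such as Top2a at -2.65. Interferon genes had 3 risen and 23 fallen of 29 tested (3 and 23 adjusted over the list alone), with a median log2 of -0.50 (adjusted p = 5.05e-05, and adjusted p = 0.066 with an estimated correlation), such as Ifit1 at -1.78. Extracellular matrix genes had 11 risen and 29 fallen of 42 tested (11 and 29 adjusted over the list alone), with a median log2 of -0.48 (adjusted p = 0.00132, and adjusted p = 0.3 with an estimated correlation), such as Dcn, which encodes decorin, at -1.87 and Fn1 at -1.52. Hypoxia and glycolysis genes had 5 risen and 18 fallen of 27 tested (5 and 18 adjusted over the list alone), with a median log2 of -0.44 (adjusted p = 0.00389, and adjusted p = 0.13 with an estimated correlation). Myofibroblast and smooth muscle genes had 2 risen and 11 fallen of 17 tested (2 and 11 adjusted over the list alone), with a median log2 of -0.23 (adjusted p = 0.00885, and adjusted p = 0.31 with an estimated correlation), such as the actin gene Actg2 at -1.83. Osteoblast genes had 4 risen and 13 fallen of 20 tested (5 and 13 adjusted over the list alone), with a median log2 of -0.22 (adjusted p = 0.0302, and adjusted p = 0.13 with an estimated correlation), and chondrocyte genes 1 risen and 6 fallen of 8 tested (1 and 6 adjusted over the list alone), with a median log2 of -0.47 (adjusted p = 0.042, and adjusted p = 0.17 with an estimated correlation), such as Col2a1 at -1.62 and Sox9 at -0.89. The osteoblast call ended among genes of at least 5 FPKM (adjusted p = 0.0978) and the osteoblast and chondrocyte calls after quantile normalization (0.0611 each), and the chondrocyte call also ended with replicate blocks (0.0621) and without ADM+DHT replicate 3 (0.0578). In all, 5472 of 10942 genes tested changed, 2548 higher and 2924 lower, with 889 and 869 at 1.5-fold or more, and the authors' deposited table has 2169 higher and 2566 lower at its q below 0.05.

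The interaction asks which genes responded to DHT differently in the 2 media, taking the difference of ADM+DHT and ADM minus that of DHT and control. Among the largest negative values were fat cell genes near 0 in regular medium, where DHT had little left to lower, so that these repeat the fall in ADM: Ephx2 at -3.90 ± 0.138, Gpd1 at -3.43 ± 0.128 and Retn at -3.28 ± 0.14. Sult1a1 rose with DHT in regular medium (2.59) and fell with it in ADM (-0.94), an interaction of -3.54 ± 0.069, and the acute-phase gene Orm1 did likewise (1.67 and -1.57), with an interaction of -3.24 ± 0.137. Both belong to families of similar genes. On the positive side, Cyp2f2, an oxidase gene, fell with DHT in regular medium (-1.27) and rose with it in ADM (1.43), an interaction of 2.71 ± 0.13. Mmp13, which DHT lowered in regular medium, stood at 12.7 ± 1.33 FPKM in ADM and 13.8 ± 0.842 in ADM+DHT, an interaction of 3.82 ± 0.135.

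Dio2 and Mfap4 also fell with DHT in regular medium but were already below 1 FPKM in ADM, with little room to fall on this scale, and their interactions were 3.87 ± 0.093 and 2.71 ± 0.249. Emp1, at 1.23 ± 0.311 FPKM in ADM, had an interaction of 4.11 ± 0.736, with ADM+DHT libraries at 13.4, 1.32 and 1.54 FPKM, and of 3.26 without ADM+DHT replicate 1. Among the genes followed throughout, Adipoq and Fabp4 had interactions of -1.57 ± 0.114 and -1.25 ± 0.066. Adipoq averaged 0.914 FPKM in control and 0.841 in DHT, so it too had little room to fall in regular medium. Fkbp5 had an interaction of -2.59 ± 0.07, its rise with DHT being 3.24 in regular medium and 0.65 in ADM. Lpl had -0.91 ± 0.071, but -0.14 (adjusted p = 0.342) with a pseudocount of 0.1, and Runx2 0.40 ± 0.099. Pparg (-0.20, adjusted p = 0.187) and Cxcl12 (0.17, adjusted p = 0.233) had no interaction past the threshold. Cebpa (-2.10 ± 0.681, adjusted p = 0.0419) lost its call without any of 9 single libraries (adjusted p 0.0631 to 0.0972).

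DHT lowered the medians of the fat metabolism lists in ADM and left them near 0 in regular medium, so their interactions were negative. In the interaction of the adipocyte identity list 1 of 29 tested members passed with a positive and 25 with a negative value, and 3 did not pass (1 and 25 adjusted over the list alone), with a median log2 of -1.24 (adjusted p = 2.65e-20, and adjusted p = 0.0085 with an estimated correlation). Lipid droplets and lipolysis had 0 positive and 12 negative values past the threshold of 17 tested (0 and 12 adjusted over the list alone). The median log2 was -1.19 (adjusted p = 3.08e-08, and 0.016 with an estimated correlation), with Lipe at -1.98. Fatty acid oxidation had 0 positive and 18 negative values past the threshold of 23 tested (2 and 19 adjusted over the list alone). The median log2 was -0.78 (adjusted p = 2.34e-12, and 0.029 with an estimated correlation), with Acadm at -1.07. Fatty acid and triglyceride synthesis had 3 positive and 12 negative values past the threshold of 23 tested (5 and 13 adjusted over the list alone), with a median log2 of -0.44 (adjusted p = 0.000353, and adjusted p = 0.03 with an estimated correlation), such as Dgat1 at -1.20. The glucocorticoid response had 3 positive and 20 negative values past the threshold of 30 tested (3 and 21 adjusted over the list alone). The median log2 was -0.63 (adjusted p = 6.44e-12, and 0.0088 with an estimated correlation), with Glul at -2.04. Here the rise with DHT in regular medium (median 0.78) was smaller in ADM (0.09).

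The size of the fat lists' negative interaction is open to a limit of the measurement, since members near 0 in regular medium had little room to fall there. Among the 29 adipocyte identity members, 18 reached a mean of 1 FPKM in a group of each medium. Over those 18 the median DHT effect was -0.05 in regular medium and -1.14 in ADM, with 14 negative interactions (median -1.03, adjusted p = 1.54e-10). Over the 13 such lipid droplet and lipolysis members the medians were 0.02 and -0.93, with 9 negative interactions (median -0.81, adjusted p = 3.58e-06). At 5 FPKM in both media 10 adipocyte members remained, 6 of them negative (median -0.55, adjusted p = 0.00261), and 7 of lipid droplets, 4 negative (median -0.29, adjusted p = 0.0126). The 19 fatty acid oxidation members left at 5 FPKM kept a median of -0.78 (adjusted p = 1.84e-09), while fatty acid and triglyceride synthesis no longer passed (adjusted p = 0.0605). With an estimated correlation 6 lists passed at 1 FPKM in both media, among them adipocyte identity (adjusted p = 0.0072), lipid droplets (0.02) and fatty acid oxidation (0.02). At 5 FPKM none passed with it, the lowest adjusted p being 0.071, which fatty acid oxidation shares.

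Positive interactions arose in 2 ways. The interferon, hypoxia and cell cycle lists had negative medians with DHT in both media, and less so in ADM: -0.62 in regular medium and -0.18 in ADM for interferon, -0.63 and -0.20 for hypoxia and glycolysis, and -0.44 and -0.31 for the cell cycle. Low levels in ADM leave less room to fall there, with 6 of 39 cell cycle, 3 of 30 interferon and 2 of 29 hypoxia members below 1 FPKM in ADM and ADM+DHT, and 31, 19 and 6 below 5 FPKM. The TGF-beta and BMP and extracellular matrix lists went from near 0 in regular medium (0.06 and 0.07) to a rise in ADM (0.37 and 0.35). Interferon genes had 19 positive and 1 negative values past the threshold of 30 tested (21 and 1 adjusted over the list alone). Their median log2 was 0.47 (adjusted p = 4.03e-06, and 0.1 with an estimated correlation), with Ifit3 at 1.43 and Ifi44 at 1.00. Over the 11 members of at least 5 FPKM in both media the median was 0.316 and the call ended (adjusted p = 0.0837). Hypoxia and glycolysis genes gave the following: 18 of 29 tested members passed with a positive and 3 with a negative value, and 8 did not pass (20 and 4 adjusted over the list alone), with a median log2 of 0.38 (adjusted p = 1.57e-05, and adjusted p = 0.072 with an estimated correlation), such as the pyruvate kinase gene Pkm at 0.80. The TGF-beta and BMP pathway had 15 positive and 5 negative values past the threshold of 30 tested (16 and 5 adjusted over the list alone), with a median log2 of 0.31 (adjusted p = 0.0093, and adjusted p = 0.059 with an estimated correlation), such as Ltbp1 at 0.72. Extracellular matrix genes had 20 positive and 13 negative values past the threshold of 42 tested (21 and 13 adjusted over the list alone), with a median log2 of 0.21 (adjusted p = 0.0238, and adjusted p = 0.36 with an estimated correlation), with Timp3 at 2.41 and Postn at -1.69, and the call ended after quantile normalization (adjusted p = 0.0601) and at 5 FPKM in both media (0.0644). Cell cycle genes had 9 positive and 0 negative values past the threshold of 39 tested (9 and 0 adjusted over the list alone), with a median log2 of 0.17 (adjusted p = 0.0169, and adjusted p = 0.4 with an estimated correlation), such as Rrm1 at 0.78. The cell cycle call ended with a pseudocount of 0.1 (adjusted p = 0.364), without ADM replicate 2 (0.0596) and without ADM+DHT replicate 1 (0.0953). In all, 2835 of 11152 genes tested passed, 1393 with a positive and 1442 with a negative interaction.

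The effect of ADM was set beside that of DHT in ADM to count genes that the androgen moved the opposite way. Of 10711 genes tested in both, 2775 changed in both, and 2071 of these changed in opposite directions against 1081 by chance from the marginal counts. Among genes that ADM raised, 1205 of 3136 (38.4%) fell with DHT, and 866 of 3363 (25.8%) that ADM lowered rose with DHT. A further 704 genes changed the same way in both, such as Fkbp5, Akr1c18 and Cxcl12, which rose, and Mki67, which fell. Asking for a fold of at least 1.5 as well left 567 in opposite directions, against 129 by chance, and 115 the same way. The 3 ADM libraries enter both comparisons, which by itself gives a negative relation: r across genes was -0.416, against -0.503 in 20 simulations of replicate noise alone. The covariance was -0.128 against -0.00709 in those simulations, which had 0 genes changed in both by limma. With the 3 ADM libraries divided between the comparisons, 1 in one and 2 in the other, no library was shared. The 6 ways of doing so gave r from -0.348 to -0.381 and covariance from -0.115 to -0.122.

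**Figure D3:**
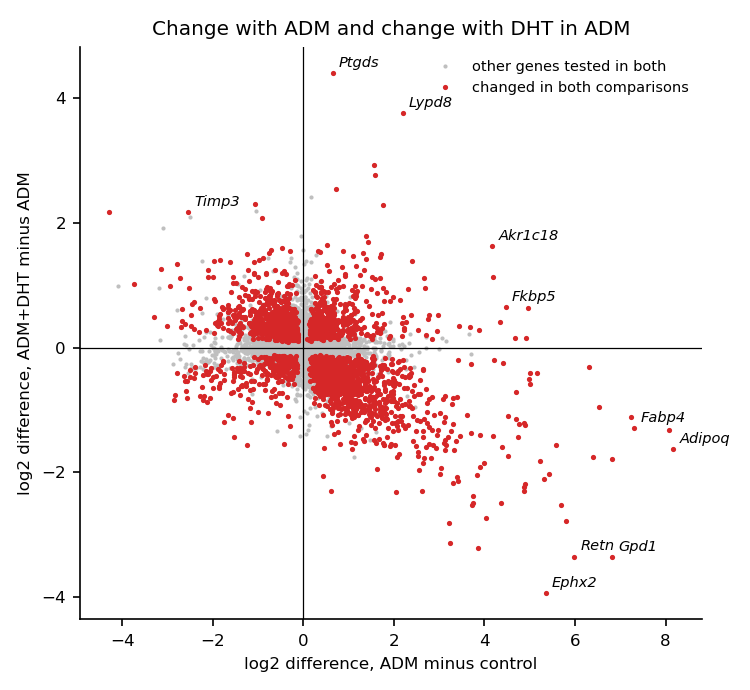
Log2 difference between ADM and control (x axis) and between ADM+DHT and ADM (y axis) for 10711 genes, each a dot, red where both passed (2775 genes). Adipoq, Fabp4, Retn, Gpd1 and Ephx2 lie at the lower right, raised by ADM and lower with DHT, and Timp3 lies at the upper left at -2.55 and 2.17.

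ADM raised 45 genes at least 16-fold, and DHT lowered 38 of them and raised 7. Their level in ADM+DHT was a median of 40.9% of that in ADM, from 4.36% for Ephx2 to 321.4% for Akr1c18. All 13 of them that are on the adipocyte identity list fell, to between 8.58% and 40.9% of the ADM level.

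The effects of DHT in the 2 media share no library and can be compared directly. Of 10405 genes tested in both, 660 rose in both media against 236 by chance (odds ratio 6.5, Fisher's exact test, two-sided p = 1e-185), and 454 fell in both against 207 (odds ratio 3.51, Fisher's exact test, p = 4.2e-74). With a fold of at least 1.5 as well, 154 rose in both against 13 by chance and 59 fell in both against 11. Genes are not independent, so these p-values describe the tables only. Ptgds, Lypd8, Sparcl1, Ctgf, Postn and Fkbp5 rose in both, and Lpl fell in both. Opposite changes numbered 284, and r across genes was 0.369. Of the genes that rose with DHT in regular medium 48.6% also rose in ADM, and of those that fell 33.6% also fell.

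**Figure D4:**
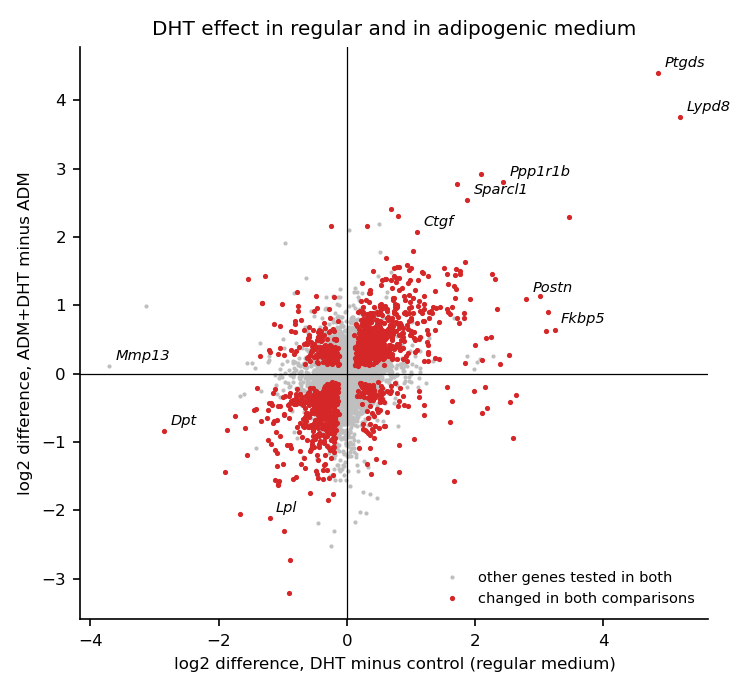
Log2 difference between DHT and control (x axis) and between ADM+DHT and ADM (y axis) for 10405 genes, each a dot, red where both passed (1398 genes). Ptgds lies at 4.85 and 4.40 and Lypd8 at 5.19 and 3.76, while Mmp13 lies at -3.71 and 0.12.

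DHT and ADM against the shared control libraries changed 2023 of 10732 genes the same way, 860 up and 1163 down, and 355 in opposite ways. Fkbp5, Postn, Sult1a1 and Glul rose in both, and Dio2, Mmp13, Emp1, Mfap4 and Ldha fell in both. The correlation across genes was 0.545 against 0.495 in 20 simulations of replicate noise with shared controls, and the covariance 0.142 against 0.00693. With the 3 control libraries divided in the same manner r was 0.459 to 0.494 and the covariance 0.131 to 0.133.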

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

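The interaction, the splits of samples and the tests on spread between replicates were planned, while the tests of the adipocyte and glucocorticoid patterns and of genes expressed in both media were chosen only after those results had been seen. Each result in the next paragraph is listed because the effect of DHT differed between the 2 media by the interaction test itself.

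The interaction was positive for 1393 genes and negative for 1442, and a positive value can be a weaker fall with DHT in ADM. By size, the positive interactions were led by Emp1 at 4.11, Dio2 at 3.87, Mmp13 at 3.82, Mfap4 at 2.71 and Cyp2f2 at 2.71 on the log2 scale. For Emp1, ADM+DHT replicate 1 alone stood at 13.4 FPKM, and the value without it was 3.26. The negative ones were led by Ephx2 at -3.90, Sult1a1 at -3.54, Gpd1 at -3.43, Retn at -3.28 and Orm1 at -3.24. Median interactions of the gene lists were -1.237 for adipocyte identity, -0.443 for fatty acid and triglyceride synthesis, -1.193 for lipid droplet and lipolysis, -0.784 for fatty acid oxidation and -0.625 for the glucocorticoid response. They were 0.31 for TGF-beta and BMP, 0.214 for extracellular matrix, 0.17 for cell cycle, 0.472 for interferon and 0.378 for hypoxia and glycolysis. With an estimated correlation the positive calls were lost (adjusted p = 0.059, 0.36, 0.4, 0.1 and 0.072 in that order).

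Genes near 0 in a medium have little room to fall there, which enlarges their interaction: Ephx2, Gpd1 and Retn in regular medium, and Dio2 and Mfap4 in ADM. It also holds for 11 of 29 adipocyte members and 4 of 17 lipid droplet members, which stayed below 1 FPKM in regular medium. Over genes of at least 1 FPKM in both media, 1275 interactions were positive and 1296 negative. All 10 lists passed at the preset correlation, with medians of -1.03 for adipocyte identity and -0.81 for lipid droplets. At 5 FPKM in both media the medians were -0.55 and -0.29, 7 lists passed at the preset correlation, and fatty acid and triglyceride synthesis, extracellular matrix and interferon did not (adjusted p = 0.0605, 0.0644 and 0.0837). With an estimated correlation, 6 of the 10 passed at 1 FPKM, adipocyte and lipid droplet lists included (adjusted p = 0.0072 and 0.02). Extracellular matrix (0.35), cell cycle (0.44), interferon (0.096) and hypoxia (0.071) did not, and at 5 FPKM 0 lists passed, the lowest adjusted p being 0.071. The negative fat list calls thus held without members below 1 FPKM in regular medium, but not at 5 FPKM with an estimated correlation. How far low levels enlarge the medians is left open, since the same limits remove 11 and 19 of the 29 adipocyte members.

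Other assignments of the libraries were counted for each comparison. For the interaction, 1 of 100 drawn assignments of the DHT label within each medium, the real one, called as many genes (2835, highest other 1676). That share is under 0.05, but the other assignments drawn mix DHT-treated and untreated libraries in at least 1 medium, which breaks up the DHT effect there. A DHT effect alike in both media on this log2 scale cancels in the interaction under the real labels. The other assignments do not cancel it, so their counts do not show how many calls arise without an interaction. The rank of the real count is therefore no test of the interaction. The assignment that swaps the DHT label in 1 medium only, which keeps treated and untreated libraries apart, was not among the 100. For the pairs, the 10 splits of 6 libraries cannot give a share under 0.05. The real split was the 1 of 10 that called as many genes in each pair. It called 3628 for ADM+DHT against ADM (highest other 1), 6825 for ADM against control (1), 2907 for DHT against control (2) and 5472 for ADM+DHT against DHT (1).

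The first pattern weighed is the lower level of adipocyte genes in ADM+DHT than in ADM. Library scaling, including the lower share of mitochondrially encoded transcripts, is argued against, because the list's median log2 difference was -1.31 after median rescaling and -1.30 before. A smaller share of adipocytes with unchanged expression in each would leave every adipocyte gene at 1 common fraction, but the differences of the 13 list members that ADM raised at least 16-fold had an SD 11.8 times their median SE, with levels from 8.58% to 40.9%. That test was narrowed to the list after the ratio over all 45 such genes (20.8) had been seen, because the others are not on the list of adipocyte markers. A biological candidate explanation, androgen action on the fat cell programme within each cell, stays open as untested, and so does a change in the number of fat cells beside it, since the tables count no cells.

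The second pattern is the rise of glucocorticoid-response genes with DHT in regular medium. RNA from ADM cultures in the DHT libraries is argued against: the 24 genes that rose in both would need 24.6% of such RNA, but Adipoq, Fabp4, Cidec, Plin1 and Cd36 stood at no more than 1.83% of the level this share brings. Library scaling is argued against as well, since the list's median was 0.79 after median rescaling. A glucocorticoid carried into the DHT cultures cannot be told apart from DHT acting on the same genes, because only 10.7% of the list moved opposite ways in DHT and ADM and no culture received an antagonist of either hormone. The biological candidate explanation, androgen action on genes that glucocorticoids also regulate, stays open as untested.

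The third pattern is a set of 213 genes, of 7693 with a group mean of at least 5 FPKM, whose libraries within a group differ by at least 2-fold (349 such cases). A single odd library is argued against, as the highest share in any library was 12%, 42 cases in ADM+DHT replicate 3. FPKM divided between overlapping gene models is a candidate explanation: 38.4% of these genes and 23.2% of the others overlap an annotated gene on their strand, an odds ratio of 2.06 (95% interval 1.54 to 2.76), although Emp1 and Cebpa overlap none. Division between several transcripts of a gene stays open, with a probability of 0.55 (SE 0.02) that such a gene has more annotated transcripts than another, too near the bound of 0.55 set beforehand, and the demand that the error be cleared was added later. Changed genes among the 213 numbered 22 in ADM+DHT against ADM, 64 in ADM against control, 22 in DHT against control and 51 in ADM+DHT against DHT, and no biological explanation was tested.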

How the results depend on the processing

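All alternatives were planned except leaving out the mitochondrially encoded genes, keeping only genes expressed in both media, dividing shared libraries between comparisons and the correlation estimated in the fit of all 12 samples, which were chosen after results had been seen. The count of changed genes stayed within 1.5 times its value under every setting run. Over the settings that keep all libraries it ranged from 2936 to 3892 for ADM+DHT against ADM, 5107 to 7210 for ADM against control, 2265 to 3202 for DHT against control, 4170 to 5692 for ADM+DHT against DHT and 1905 to 2836 for the interaction. The 1905 came from the 6489 genes of at least 5 FPKM in both media, of which 902 had a negative interaction in place of 1442, as fewer genes were tested and low fat genes left out. At 1 FPKM in both media 2571 of 10405 passed. Quantile normalization turned the direction of 1 call in each comparison but DHT against control, and a pseudocount of 0.1 turned 2 interaction calls. DESeq2, planned for count tables, was not run because the tables hold no counts.

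Asking for a fold of at least 1.5 as well left 567 of the 2071 genes that ADM and DHT in ADM changed in opposite ways, and 213 of the 1114 that DHT changed the same way in both media, since fewer genes can then pass. Dividing the ADM libraries between the comparisons left 1485, 1470 and 1520 opposite changes with replicate 1, 2 or 3 alone set against control, and 1161, 1137 and 1194 with it alone set against ADM+DHT. Changes the same way by DHT and ADM went from 2023 to 966, 861 and 953 with 1 control library set against DHT and to 1328, 1573 and 1363 with 1 set against ADM. In these fits 1 arm is a single library, so the spread comes from the other group alone and the counts do not test the overlap. With an estimated correlation, the lists past the threshold went from 12 to 0 for ADM+DHT against ADM, 13 to 2 for ADM against control, 6 to 3 for DHT against control, 13 to 4 for ADM+DHT against DHT and 10 to 5 for the interaction. With it estimated from all 12 samples the counts were 6, 8, 3, 6 and 5. The cause of the loss was not tested further. In ADM+DHT against ADM the TGF-beta and BMP estimate was -0.004, under the preset 0.01, yet its unadjusted camera p went from 8.04e-06 to 0.0074. A lost call thus need not mean correlated members. Adipocyte identity had 0.191 (camera p from 3.66e-20 to 0.015). With 12 samples (8 residual degrees of freedom, not 4) both had adjusted p = 0.0079. The interaction of Akr1c18 reversed at a pseudocount of 0.1, from 1.24 to -0.105 (adjusted p = 0.886), where its control level of 0.0442 FPKM lies below the pseudocount. Of 4806 values of named genes under the other settings that keep all libraries, 4780 kept direction and side of the threshold, 15 lost their call, 10 gained one and 1 reversed. Of 3866 values with a library left out, 3817 kept both, 42 lost their call and 7 gained one.

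Leaving out each library in turn gave 2915 to 3137 changed genes for ADM+DHT against ADM (1453 to 1592 higher, 1462 to 1545 lower), 6255 to 6454 for ADM against control (2878 to 3014 higher, 3351 to 3484 lower), 2095 to 2668 for DHT against control (1003 to 1240 higher, 1091 to 1428 lower), 4760 to 4932 for ADM+DHT against DHT (2177 to 2289 higher, 2523 to 2679 lower) and 2527 to 2739 for the interaction (1215 to 1334 positive, 1294 to 1405 negative). Opposite changes by ADM and DHT in ADM ranged from 1700 to 2006, and changes by DHT the same way in both media from 871 to 1025. Lists past the threshold ranged from 11 to 13, 11 to 13, 6 to 8, 12 to 13 and 9 to 11 in the order above.

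Replicate numbers share no stated origin. Over 18 pairs of samples with the same number in different groups, deviations from group means correlated from -0.13 to 0.14, against -0.12 to 0.19 for different numbers, and 3 of 12 libraries correlated best with their own number. With replicate number as a block, 1511 genes were higher and 1522 lower in ADM+DHT against ADM, 3093 and 3619 in ADM against control, 1211 and 1331 in DHT against control, 2313 and 2629 in ADM+DHT against DHT, and 1349 and 1401 in the interaction. The unknown depth leaves no floor for genes listed at 0, and differences of genes below 1 FPKM rest on the pseudocount.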

Other observations

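The 7 gene groups behind the next paragraphs were defined, and their tests chosen, after the results had been seen, so they describe these libraries only. By camera with an estimated correlation, no group named here passed after adjustment over the 7 groups of a comparison, and the counts are of single genes.

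Nuclear genes of the respiratory chain and ATP synthase, which make the partners of the mitochondrially encoded subunits, moved in the same directions as the fat cell genes. Of 76 tested, 69 rose and 2 fell in ADM against control (median log2 0.62, adjusted p = 0.22), and 0 rose and 66 fell in ADM+DHT against ADM (median -0.54, adjusted p = 0.098). DHT in regular medium lowered 19 of them and raised 0 (median -0.11, adjusted p = 0.6). Their interaction was negative for 55 and positive for 1 (median -0.41, adjusted p = 0.066). Of the 13 mitochondrially encoded genes, 12 rose in ADM (median 0.84, adjusted p = 0.14) and 12 fell in ADM+DHT against ADM (median -0.34, adjusted p = 0.098). With DHT in regular medium their median was 0.06 and 0 of 13 passed. In ADM+DHT against DHT 13 of these rose (median 0.46), as did 45 of the nuclear genes, while 3 fell (median 0.21).

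Genes of protein synthesis were lower in adipogenic medium. All 80 tested genes of cytosolic ribosomal proteins fell in ADM against control (median -0.64, adjusted p = 0.23) and in ADM+DHT against DHT (median -0.52, adjusted p = 0.21). DHT lowered 28 of them in regular medium, while in ADM 2 rose and 8 fell with it. Of 17 genes of transfer RNA synthetases, which charge transfer RNAs with amino acids, 17 fell in ADM against control (median -0.96, adjusted p = 0.14), 12 in DHT against control (median -0.23, adjusted p = 0.55) and 15 in ADM+DHT against DHT (median -0.57, adjusted p = 0.12), and 0 rose. In ADM+DHT against ADM 6 rose and 0 fell (median 0.10, adjusted p = 0.26). Their interaction was positive for 9 and negative for 0 (median 0.28, adjusted p = 0.066). Among 21 replication-dependent histone genes, many of them near-identical, 1 rose and 10 fell in ADM+DHT against ADM (median -0.37, adjusted p = 0.098), and 2 rose and 0 fell in DHT against control (median 0.03). Of 27 tested in ADM against control 11 rose and 11 fell (median 0.36), and of 23 in ADM+DHT against DHT 8 rose and 10 fell (median -0.16). Of 37 proteasome genes 3 rose and 6 fell in ADM+DHT against ADM, 8 and 6 in ADM against control, 0 and 3 in DHT against control and 8 and 4 in ADM+DHT against DHT. Of 14 genes of antigen presentation 1 rose and 1 fell, 2 and 5, 1 and 4, and 4 and 3 in the same order.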
